A study of Drosophila melanogaster with 13 samples.

How the data were processed

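RNA was sequenced from heads of Drosophila melanogaster aged 5 days. Per the labels, the Gal4 driver GMR, which acts in the pupal retina and the adult eye, expressed RNAi against Rab5 in 5 samples and against Rab7 in 4 samples. The other 4 samples carried the driver over a wild-type chromosome and are the controls. Flies were kept at 25 °C, and libraries were made from 1.3 ug of total RNA with a SMARTer mRNA kit, per the labels' protocols. The labels name no batch and do not say whether samples came from separate crosses or flies, so p-values measure the spread between these samples, which may be technical.

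The authors deposited FPKM, a value scaled to gene length and library size, for 18344 genes in each sample, and gene coordinates and lengths in a table of the whole series. The only tool in the submitters' processing notes is CASAVA, without a version. The aligner, the counter, the strand setting, the genome build and the annotation are not given in the sources used here. The 13 columns of per-sample values in the series table were not used. There, 591 gene models have no name, 5 gene names had been turned into dates and were repaired through their identifiers, and 89 chromosome cells were damaged and are not printed. Of the 17626 identifiers also found in a BDGP6 annotation, 17486 (99.2%) had the same coordinates there; coordinates below are those of the deposited table.

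Each deposited FPKM value times the gene's length was a whole multiple of 1 step per library. All 182918 values above 0 came out whole within 0.05, with a largest deviation of 0.0137, so reads on genes were recovered exactly. The totals behind the deposited FPKM equalled the median-of-ratios size factors of those reads, over the 11577 genes above 0 in every library, times the geometric mean of the read sums (largest relative difference 1.5e-08). The FPKM values therefore were already scaled across libraries before deposit. Recovered reads per library ran from 17138630 to 21410768. A gene of 1 kilobase with 1 read has an FPKM near 0.05 in every library. Floors given for a level of 0 assume 3 reads and cover counting error only.

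The design written before the data were examined assumed counts. The files hold FPKM, so its stated alternative for FPKM was used. Values were taken as log2(FPKM + 1) for the 10038 genes with a mean FPKM of at least 1 over the 13 libraries. limma 3.58.1 with a mean-variance trend and robust empirical Bayes was fitted to all 3 groups together in R 4.3.3, without covariates. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 within each comparison. Every log2 difference below is on the log2(FPKM + 1) scale, which understates changes of genes with low values, and SE is its standard error from limma. FPKM means are given with their SD.

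The same fit served the tests of 38 gene lists fixed before the data were examined, of which 35 had at least 5 tested members. Lists were tested with limma's camera with a preset correlation of 0.01, with camera using an estimated correlation, and with fry, each adjusted by Benjamini-Hochberg over lists. With an estimated correlation no list passed in any comparison, and the lowest adjusted p was 0.63 for Rab5 RNAi against control, 0.60 for the libraries labelled Rab7 RNAi against control and 0.35 between the RNAi groups. camera and fry both called 6, 1 and 7 lists in these 3 comparisons. In Rab5 RNAi against control, fry did not call ribosomal proteins (fry adjusted p = 0.185), oxidative phosphorylation (0.181) or heat shock genes (0.0557). For the libraries labelled Rab7 RNAi, eye pigment was the only list called by both. Counts within lists are over all genes tested and, beside them, adjusted over the list alone. A few list members were found only through older symbols.

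Genes were named by a rule fixed before the data were examined. It took Rab5 and Rab7, every tested tubulin, and up to 3 leading members of each list that camera called or that held at least 3 called genes. It also took the 6 higher and 6 lower called genes with the largest change among those with a log2 CPM of at least 2 and no overlap between groups, or 4 and 4 between the RNAi groups. Some list members were left out for length, and some are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

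The fit was tested on simulated data with 200 changed genes. For Rab5 RNAi against control, over 10018 to 10051 genes run, it recovered 51.5%, 77.3% and 98.4% of genes changed 1.5-fold, 2-fold and 4-fold. For the libraries labelled Rab7 RNAi against control the shares were 49.0%, 81.8% and 93.3%, and between the RNAi groups 58.0%, 84.7% and 95.2%. False calls made up 2.92% to 6.90% of the calls. The list test called the 1 changed list and 0 of 34 random lists. Simulated genes varied independently of each other, so this does not bear on lists whose members vary together. For Rab5 RNAi against control the estimated correlation was 0.53 in the phototransduction list and 0.575 in the list of cytosolic ribosomal proteins.

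Replicates of a group were checked for repeated libraries. The chi-square per degree of freedom between any pair in a group was at least 9.92, so no pair agreed within sampling noise. Other settings chosen before the data were examined were the trimmed mean of M values and upper-quartile scaling, no filter, a mean FPKM of at least 5, a mean CPM of at least 5, a pseudocount of 0.1, limma-voom on the recovered reads, only the 2 groups compared, the replicate number as a block, and leaving out each library. Scaling by plain read totals and settings based on 2 sets of libraries were added after the data were seen. For shared responses against the same controls, 100 simulations of unchanged groups and all 6 divisions of the controls, 2 for each comparison, were run. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.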

Results

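The series asks how Rab proteins bear on microtubules and tubulin expression in flies with a degenerating eye. Heads of 5-day-old adults with eye-directed RNAi against Rab5 (n = 5), with eye-directed RNAi against Rab7 (n = 4) and with the driver alone (n = 4) were sequenced. Reads recovered from the deposited FPKM were 17138630, 17596962, 17632996, 18608666 and 17761709 in Rab5 RNAi replicates 1 to 5. They were 19312214, 17909194, 21410768 and 17928091 in the libraries labelled Rab7 RNAi, replicates 1 to 4, and 19025418, 18956120, 18116401 and 17411145 in controls 1 to 4. Whole heads hold many tissues besides the eye, and every value is an average over them. The mitochondrial large ribosomal RNA took 4.37% ± 1.45 (SD, n = 5) of reads in Rab5 RNAi, 3.72% ± 1.27 (SD, n = 4) in the libraries labelled Rab7 RNAi and 2.21% ± 0.44 (SD, n = 4) in controls.

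Rab5, the GTPase of early endosomes (FBgn0014010, 2L 2359142 to 2365273, minus strand), had 57.7 FPKM ± 5.56 (SD, n = 5) in Rab5 RNAi and 115.5 FPKM ± 4.54 (SD, n = 4) in controls. It fell by 0.99 on the log2 scale (SE 0.09, limma adjusted p = 1.9e-05), and every Rab5 RNAi library lay below every control. Rab7, the GTPase of late endosomes (FBgn0015795, 3R 23993008 to 23995452, plus strand), had 97.7 FPKM ± 9.54 (SD, n = 4) in the libraries labelled Rab7 RNAi and 99.97 FPKM ± 3.93 (SD, n = 4) in controls. The log2 difference was -0.04 (95% interval -0.21 to 0.13, limma adjusted p = 0.88), so no fall of the Rab7 transcript was detected in these whole heads. The interval excludes a fall of the size seen for Rab5 in Rab5 RNAi, but not a small one. A fall confined to the eye would be diluted by the rest of the head. These 4 libraries are therefore called the Rab7-labelled libraries, and every direction given for them describes the label, not a measured loss of Rab7. Rab7 in Rab5 RNAi was 113.5 FPKM ± 5.51 (SD, n = 5), which did not pass the test (log2 0.18, adjusted p = 0.12); it passed only when libraries were scaled to plain read totals (adjusted p = 0.017).

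**Figure D1:**
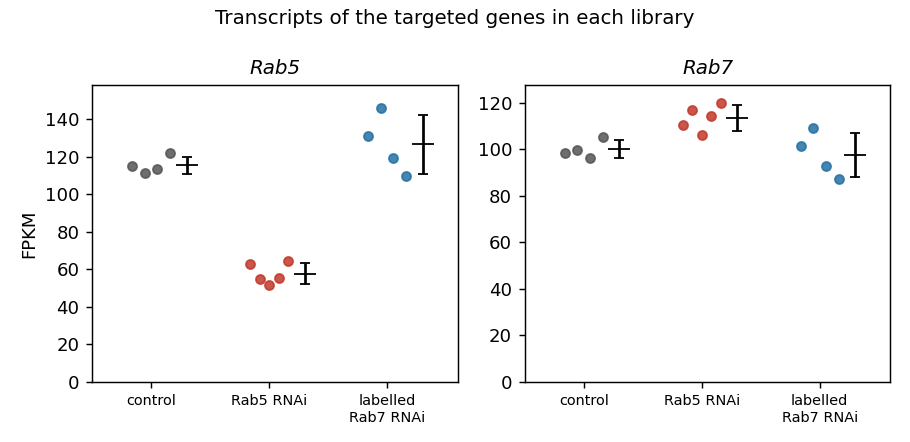
FPKM of Rab5 and Rab7 in each library; each point is 1 library, and the line and bar beside the points are the mean and SD. Rab5 averages 57.7 FPKM in Rab5 RNAi against 115.5 in controls, while Rab7 averages 97.7 FPKM in the Rab7-labelled libraries against 99.97 in controls.

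After the data were seen, libraries of every group were found to differ along 1 shared direction, the first component of the values left after removing group means, which held 35.3% of that variance. Set 2 is used here for the 6 libraries with a positive score, Rab5 RNAi 1 and 5, Rab7-labelled 1 and 4 and controls 1 and 4, and set 1 for the other 7. Control 1 scored 0.0057 and could as well belong to set 1. With groups held fixed, the phototransduction list had a median log2 difference of -0.39 between set 2 and set 1, the heat shock list -0.38 and the muscle list 0.49. Act57B, a muscle actin, had 1438 to 1574 FPKM in set 2 without control 1 and 653 to 846 FPKM in the other libraries.

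**Figure D2:**
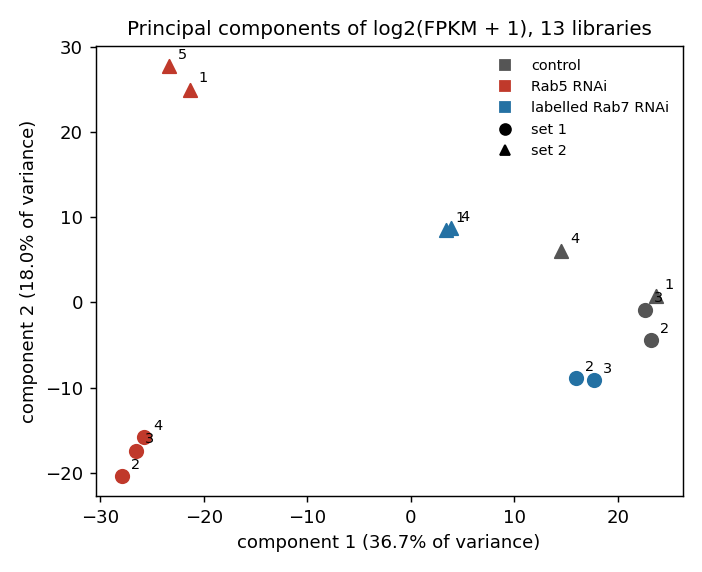
Principal components 1 and 2 of log2(FPKM + 1) over the 13 libraries, with 36.7% and 18.0% of the variance; colours are groups, circles set 1, triangles set 2 and numbers replicates. Set 2 is defined by the residual component, not by the axes drawn here.

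The first comparison asks what changed in heads with Rab5 RNAi. Phototransduction genes, which turn light into the photoreceptor's electrical response, fell in most cases: of 32 tested, 26 fell, 2 rose and 4 did not pass, with a median log2 difference of -1.70. Adjusted over the list alone, 28 fell and 2 rose. Rh4, an ultraviolet opsin of the R7 photoreceptor (FBgn0003250, 3L 16852527 to 16862517), went from 384.1 FPKM ± 120 (SD, n = 4) in controls to 23.2 FPKM ± 9.21 (SD, n = 5), a log2 fall with a value of -4.02 (SE 0.33, limma adjusted p = 9.9e-06). Rh3, the other R7 ultraviolet opsin, fell by 1.79 (SE 0.16), and Ggamma30A, a subunit of the visual G protein, fell by 1.21 (SE 0.13). Chosen after their values were seen, ninaE, the main opsin of the outer photoreceptors, fell by 3.69 (SE 0.56) and the light-gated channel trp fell by 2.76 (SE 0.37). Rh5 and Rh6 were chosen after their values were seen as well. Rh5 also fell (log2 -2.47, limma adjusted p = 0.041), whereas Rh6 had a log2 difference of -0.49 and did not pass (limma adjusted p = 0.14). santa-maria, a scavenger receptor for carotenoids, and Gprk1, a receptor kinase, both also chosen after their values were seen, rose by 0.69 and 0.38. The camera adjusted p of the list was 4.6e-17, and adjusted p = 0.63 with an estimated correlation. The phototransduction list was also lower in set 2 by a median of -0.39; among set 1 libraries with control 1 its median in Rab5 RNAi was -1.26.

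**Figure D3:**
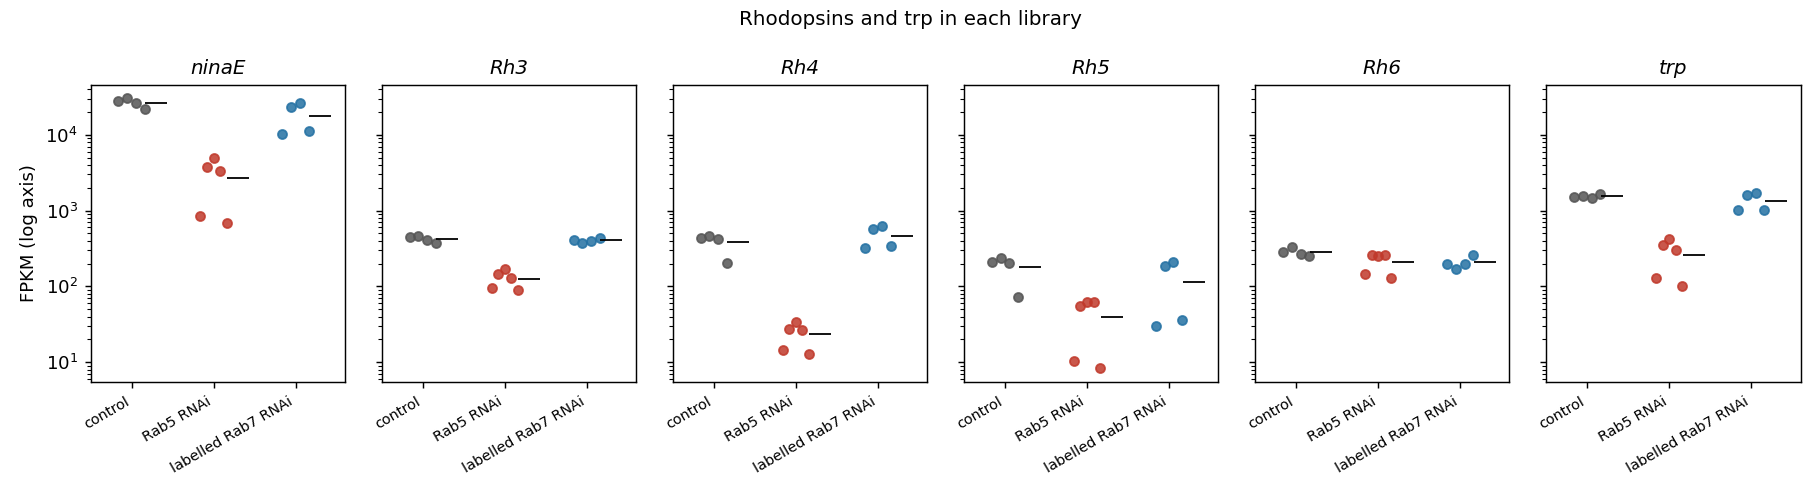
FPKM on a log axis of the 5 compound eye rhodopsins and trp in each library; points are libraries and the line is the mean, with no error bar. ninaE, Rh3, Rh4, Rh5 and trp are lower in Rab5 RNAi than in controls, while Rh6 averages 208.6 FPKM in Rab5 RNAi and 282.2 in controls and did not pass the test.

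Genes of photoreceptor structure fell in 6 cases and rose in 1 of 17 tested (9 and 1 adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.78 with an estimated correlation). Among them eys, a matrix protein of the space between rhabdomeres, fell by 1.09 (SE 0.09), prom by 1.61 (SE 0.22) and Patj by 0.61 (SE 0.08). The list did not pass among set 1 libraries alone (adjusted p = 0.19). The largest fall by the rule, on the log2(FPKM + 1) scale, was Pdh, the retinal pigment cell dehydrogenase of retinoid recycling (FBgn0011693, 3L 16353233 to 16354297), from 312.8 FPKM ± 102 (SD, n = 4) to 7.66 FPKM ± 2.49 (SD, n = 5), at a log2 of -5.18 (SE 0.27).

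Some secreted immune peptides were lower in Rab5 RNAi. Of 31 antimicrobial peptide genes tested 17 fell and 1 rose (17 and 3 adjusted over the list alone), with a median log2 of -1.83 and a camera adjusted p of 4.7e-05, but adjusted p = 0.78 with an estimated correlation. IM1 went from 430.5 FPKM ± 24.5 (SD, n = 4) to 56.05 FPKM ± 10.98 (SD, n = 5), at a log2 of -2.94 (SE 0.32). CG5791, an immune-induced peptide, went from 64.9 FPKM ± 7.77 (SD, n = 4) to 3.20 FPKM ± 1.07 (SD, n = 5), CG43202 had a log2 of -1.95 (SE 0.18), and the antifungal peptide Drs of -3.84 (SE 0.76). Def, named after its value was seen, rose by 1.68 (SE 0.48). Fat body markers fell in 3 cases and rose in 0 of 12 (5 and 1 adjusted over the list alone; camera adjusted p = 0.015, and adjusted p = 0.78 with an estimated correlation; adjusted p = 0.055 without control 1). They included the yolk protein Yp3 (log2 -1.86, SE 0.46), which was also lower in set 2 (-1.10, SE 0.24), Lpin (-0.39) and the fatty acid synthase FASN1 (-0.59), whose call ended under 9 alternatives with adjusted p up to 0.12, while that of Lpin ended in set 1 alone (adjusted p = 0.0504). SPH93, a serine protease homologue, went from 38.7 FPKM ± 6.47 (SD, n = 4) to 0.324 FPKM ± 0.295 (SD, n = 5).

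Some heat shock genes, glutathione S-transferases and genes of apoptosis and JNK signalling were higher in Rab5 RNAi. Of 24 heat shock genes 10 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.51 and a camera adjusted p of 6.3e-04, but adjusted p = 0.78 with an estimated correlation. Hsp67Bc rose by 0.87 (SE 0.15), and Hsp70Ba and Hsp70Bb both by 1.18 (SE 0.20 and 0.23); the Hsp70 copies are nearly identical, and reads can be split between them. The heat shock list was lower in set 2 by a median of -0.38, and its median in Rab5 RNAi was 0.69 among set 1 libraries alone. Of 32 glutathione S-transferases 11 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 6.5e-04, and adjusted p = 0.78 with an estimated correlation). GstE1 rose from 51.1 FPKM ± 22.1 (SD, n = 4) to 532.9 FPKM ± 156 (SD, n = 5), GstD5 had a log2 of 2.87 (SE 0.47) and GstD9 of 0.47 (SE 0.07); this family too holds close copies. Of 28 genes of apoptosis and JNK signalling 8 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 6.3e-04, and adjusted p = 0.63 with an estimated correlation). They included the JNK-responsive genes Mmp1 (log2 1.18, SE 0.16) and Ets21C (0.97, SE 0.13) and the TNF receptor grnd (0.52, SE 0.09).

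Of 86 cytosolic ribosomal protein genes 7 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.15 and a camera adjusted p of 4.7e-05, but adjusted p = 0.78 with an estimated correlation. RpS29 rose by 0.53 (SE 0.13) and RpLP2 by 0.43 (SE 0.11). The calls of RpS29 and RpLP2 ended in set 1 alone (adjusted p = 0.060 and 0.14), and that of RpLP2 without control 3 (adjusted p = 0.0502). Of 63 nuclear genes of oxidative phosphorylation 8 fell and 1 rose, with the same counts adjusted over the list alone; the median was -0.14 (camera adjusted p = 6.5e-04, and adjusted p = 0.78 with an estimated correlation; adjusted p = 0.12 without control 2). ND-51 fell by 0.47 (SE 0.09) and ND-42 by 0.32 (SE 0.08), and COX7AL, a close copy of another subunit, rose by 1.02 (SE 0.23). The ND-42 call ended under 4 alternatives (adjusted p up to 0.093).

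Tubulins are the subject of the series' question. Of 9 tested in Rab5 RNAi, only betaTub97EF was called (FBgn0003890, 3R 27967008 to 27988384, minus strand), under every scaling run. It had 21.02 FPKM ± 3.73 (SD, n = 5) against 35.3 FPKM ± 2.56 (SD, n = 4) in controls, a log2 of -0.74 (SE 0.13, limma adjusted p = 1.4e-03). Under plain read totals alphaTub67C was called as well (adjusted p = 0.040), as it was without Rab5 RNAi 3 (adjusted p = 0.013); in the fit reported it had a log2 of 0.43 and an adjusted p of 0.068. The abundant alphaTub84B had 855.1 FPKM ± 163 (SD, n = 5) against 818.5 FPKM ± 44.5 (SD, n = 4), and betaTub56D 480.7 FPKM ± 134 (SD, n = 5) against 448.5 FPKM ± 37.0 (SD, n = 4); neither passed. alphaTub84D (log2 -0.20), CG7794 (0.40), betaTub60D (-0.56), betaTub85D (0.19) and gammaTub23C (0.03) did not pass either. CG7794 passed under 3 alternatives (limma adjusted p from 0.026 to 0.041). These were leaving out Rab5 RNAi 5, the replicate number as a block, and set 1 with control 1. betaTub60D passed without Rab5 RNAi 4 (limma adjusted p = 0.033). The list as a whole did not pass (camera adjusted p = 0.89); its median was 0.04, its mean -0.04 and the direction of the test down. Tubulin genes are close copies of each other, and reads can be split between them.

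The next genes were chosen after their values were seen, because of the series' question. Among 37 genes of microtubule-associated proteins 3 rose and 3 fell in Rab5 RNAi, with the same counts adjusted over the list alone (camera adjusted p = 0.50). The kinase sgg fell by 0.48 (SE 0.07) and the spectraplakin shot by 0.47 (SE 0.10), and the centrosomal protein tacc rose by 0.41 (SE 0.08). Of 48 genes of endosomal trafficking 3 rose and 4 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.89), among them the ESCRT component Hrs (log2 -0.91, SE 0.15), the syntaxin Syx13 (0.49) and Ccz1 (-0.33; adjusted p = 0.061 in set 1 alone). Of 24 other Rab genes Rab32 (-1.12, SE 0.17), Rab14 (-0.32; adjusted p up to 0.086 under 2 alternatives) and Rab10 (0.39) were called, with 2 higher and 2 lower in all. Of 38 lysosomal genes 6 rose and 4 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.51); Vha68-2, VhaAC45 and ATP6AP2, all of the vacuolar proton pump, rose by 0.69, 0.36 and 0.37. In the JAK/STAT list 2 rose and 2 fell of 11: the cytokine upd3 had a log2 of 1.90 (SE 0.15), its target Socs36E of 0.91 (SE 0.08), and the stress protein TotX of -2.15 (SE 0.32).

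In all, limma called 1761 of 10038 genes in Rab5 RNAi, 829 higher and 932 lower, and 389 of them had a log2 difference of at least 1 in size. The groups did not overlap in 1489 of the called genes; over all genes tested 18.6% did not overlap, where chance gives 1.59%. Besides Pdh and GstE1, the rule for the largest changes named y (FBgn0004034), the yellow pigment gene, at 31.4 FPKM ± 13.2 (SD, n = 5) against 0.0874 ± 0.0456 (SD, n = 4). It also named Cyp6a17, a cytochrome P450 (FBgn0015714), at 15.0 FPKM ± 4.06 (SD, n = 5) against 0.0719 ± 0.0301 (SD, n = 4), Osi19 (log2 3.69, SE 0.38) and CG9701 (log2 3.05, SE 0.40). mthl8, a receptor of the Methuselah family (FBgn0052475, 3L 22428 to 26308), had 0 reads in all 5 Rab5 RNAi libraries and 31.4 FPKM ± 3.15 (SD, n = 4) in controls, which puts it at least 3328-fold lower with a floor of 3 reads over the group. With plain read totals 67.6% of calls were higher, against 47.1% with the deposited scaling. The label gives 1 RNAi genotype per gene, so the RNAi and the line's genetic background cannot be told apart.

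The second comparison asks the same of the Rab7-labelled libraries, in which no fall of Rab7 itself was detected. Of 86 cytosolic ribosomal protein genes 3 rose and 0 fell (31 and 0 adjusted over the list alone), with a median log2 of 0.30. The camera adjusted p was 1.4e-19, but adjusted p = 0.60 with an estimated correlation, and the list did not pass fry (fry adjusted p = 0.092). RpLP2 had 2333 FPKM ± 145 (SD, n = 4) against 1637 FPKM ± 241 (SD, n = 4), a log2 of 0.52 (SE 0.11, limma adjusted p = 0.026); RpL28 had 0.41 (SE 0.10). These 2 calls ended under 7 and 20 alternatives, with adjusted p up to 0.35 and 0.42.

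Some blood cell genes were lower in the Rab7-labelled libraries. Of 13 hemocyte markers 4 fell and 0 rose (6 and 1 adjusted over the list alone; camera adjusted p = 6.9e-04, and adjusted p = 0.60 with an estimated correlation). PPO1, a prophenol oxidase, went from 7.33 FPKM ± 1.56 (SD, n = 4) to 1.19 FPKM ± 0.306 (SD, n = 4), at a log2 of -1.92 (SE 0.20). The receptor Sr-CI and the clotting factor Hml both had -1.28 (SE 0.23 and 0.27); among set 1 libraries alone they did not pass (adjusted p = 0.22 and 0.47), and the call of Hml ended under 8 alternatives in all. Antimicrobial peptides had a median of -0.81 but 0 called of 31, and 0 adjusted over the list alone (camera adjusted p = 8.3e-05, and adjusted p = 0.60 with an estimated correlation). The list's median was -0.09 in set 1 alone (adjusted p = 0.74). The leading members were AttC (log2 -2.54, adjusted p = 0.077), CG18107 (-0.77, adjusted p = 0.098) and Drs (-2.50, adjusted p = 0.12); AttC passed without Rab7-labelled 3 (adjusted p = 0.033), and CG18107 and Drs without Rab7-labelled 2 (adjusted p = 0.043 and 0.048).

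Of 16 eye pigment genes 2 rose and 0 fell, with a median of 0.18 (4 and 0 adjusted over the list alone; camera adjusted p = 2.6e-03, and adjusted p = 0.60 with an estimated correlation). se, an enzyme of the red drosopterins, went from 1.95 FPKM ± 0.615 (SD, n = 4) to 22.9 FPKM ± 10.2 (SD, n = 4), at a log2 of 2.94 (SE 0.29). The tryptophan oxygenase gene v, also in the fixed list of transgene markers, of which 2 of 4 (v and y) were higher here, had a log2 of 1.18 (SE 0.19), and cl 0.51, which did not pass (adjusted p = 0.067) but did under 5 alternatives (adjusted p from 0.021). Of 24 heat shock genes only Hsp70Bb was called (log2 1.65, SE 0.25; 2 adjusted over the list alone), with a list median of 0.30 (camera adjusted p = 3.2e-03, and adjusted p = 0.60 with an estimated correlation). The heat shock list was lower in set 2 by a median of -0.38, and its median in these libraries was 0.54 among set 1 alone; without Rab7-labelled 3 it did not pass (adjusted p = 0.061), nor without Rab7-labelled 2, nor without control 4 (adjusted p = 0.074). Glutathione S-transferases rose in 4 cases and fell in 0 of 32 (7 and 1 adjusted over the list alone; camera adjusted p = 4.2e-03, and adjusted p = 0.60 with an estimated correlation), with GstT4 at 0.73, GstE1 at 1.17 and GstE11 at 20.98 FPKM ± 6.80 (SD, n = 4) against 8.13 FPKM ± 2.15 (SD, n = 4). The list did not pass in set 1 alone (adjusted p = 0.14), nor did GstE11 there (adjusted p = 0.19), and GstE1 did not pass without any 1 of 7 libraries (adjusted p up to 0.10).

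The remaining lists called by camera in these libraries were the mitochondrial genome, glycolysis and glia. Mitochondrial transcripts had a median of 0.32 with 0 called of 22, glycolysis genes 0.19 with 0 called of 17 (1 adjusted over the list alone), and glia markers -0.23 with 1 lower of 16 (5 adjusted over the list alone). Their camera adjusted p were 4.0e-03, 0.010 and 0.012, and adjusted p = 0.60 with an estimated correlation for each. None held throughout: mitochondrial transcripts did not pass without Rab7-labelled 2 (adjusted p = 0.080), glycolysis genes without Rab7-labelled 4 (adjusted p = 0.14) and glia markers without control 4 (adjusted p = 0.070). The called glial gene was the GABA transporter Gat (log2 -0.72, SE 0.16); its call ended under 6 alternatives (adjusted p up to 0.091). Phototransduction genes had a median of -0.17 with 0 called of 32, and 0 adjusted over the list alone (camera adjusted p = 0.19). Chosen after its values were seen, ninaE had 17704 FPKM ± 8278 (SD, n = 4) against 26557 FPKM ± 3462 (SD, n = 4).

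Of the 9 tubulins only betaTub60D was called in the Rab7-labelled libraries (FBgn0003888, 2R 24305881 to 24313099, plus strand), under every scaling run. It had 4.90 FPKM ± 1.41 (SD, n = 4) against 9.93 FPKM ± 1.60 (SD, n = 4), a log2 of -0.91 (SE 0.22, limma adjusted p = 0.042). The call was fragile: it ended under 13 alternatives, among them leaving out any control or Rab7-labelled 1, 2 or 4 (adjusted p = 0.056 to 0.14), and in set 1 alone its log2 was -0.53 (adjusted p = 0.54). The other 8 had log2 differences from -0.20 for betaTub97EF to 0.33 for alphaTub67C. The list did not pass (camera adjusted p = 0.88), with a median of 0.09, a mean of -0.02 and the direction of the test up. Microtubule-associated genes had 1 called of 37, tacc (log2 0.32, adjusted p = 0.0497), and 0 adjusted over the list alone (camera adjusted p = 0.999), with a median of -0.04 and a mean of 0.01. Genes of endosomal trafficking had 0 called of 48 (camera adjusted p = 0.12), and other Rab genes 0 of 24.

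**Figure D4:**
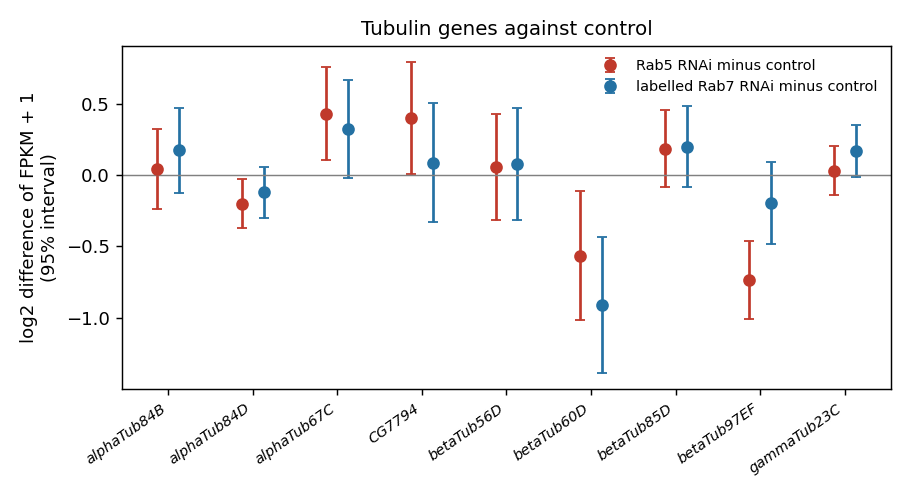
Log2 differences from control, with 95% intervals, of the 9 tested tubulin genes in Rab5 RNAi and in the Rab7-labelled libraries. Under the deposited scaling only betaTub97EF (-0.74, Rab5 RNAi) and betaTub60D (-0.91, Rab7-labelled) passed the test across all genes; with plain read totals alphaTub67C passed as well in Rab5 RNAi.

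limma called 322 of 10038 genes in the Rab7-labelled libraries, 165 higher and 157 lower, with 102 at a log2 of at least 1 in size. The groups did not overlap in 308 of them; over all genes tested 13.8% did not overlap, where chance gives 2.86%. On the log2(FPKM + 1) scale, the largest rises by the rule were CG11313 (log2 4.16, SE 0.41), y (3.38, SE 0.34), se, CG4962 (2.50, SE 0.34) and a pair of gene models without a name. One of these models lies on 3L from 12957887 to 12960027 (log2 3.30, SE 0.42), and the location of the other (2.58, SE 0.14) is damaged in the table. The largest falls were mthl8, with 0 reads in all 4 libraries and at least 2654-fold lower with a floor of 3 reads over the group, CG6654 (-2.96, SE 0.08), a gene model without a name on 3L from 23078801 to 23082324 (-2.20, SE 0.19), Osi2 (-2.06, SE 0.27), PPO1 and CG13833 (-1.31, SE 0.22). The count was 559 when only the 2 groups compared were fitted, and 179, 193, 177, 197 and 167 without Rab7-labelled 1, Rab7-labelled 4, control 1, control 2 and control 3. With limma-voom on the recovered reads y (adjusted p = 0.056) and the first unnamed model (adjusted p = 0.052) did not pass.

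The third comparison set the RNAi groups against each other and so tests their differences directly. Phototransduction genes were lower in Rab5 RNAi than in the Rab7-labelled libraries in 24 of 32 cases and higher in 0 (25 and 1 adjusted over the list alone), with a median log2 of -1.37. The camera adjusted p was 3.6e-18, but adjusted p = 0.39 with an estimated correlation; the list was also lower in set 2 by a median of -0.39. Rh4 had 23.2 FPKM ± 9.21 (SD, n = 5) against 467.4 FPKM ± 158 (SD, n = 4), a log2 of -4.30 (SE 0.33). Hemocyte markers were higher in 6 of 13 cases and lower in 0 (7 and 0 adjusted over the list alone; camera adjusted p = 1.9e-04, and adjusted p = 0.51 with an estimated correlation). Rab5 itself had a log2 of -1.12 (SE 0.09) and Rab7 of 0.22 (adjusted p = 0.083; 0.043 without Rab7-labelled 2 and 8.4e-03 under plain read totals). Of the 9 tubulins betaTub97EF was called (log2 -0.54, SE 0.13, limma adjusted p = 0.014), a call that ended without Rab7-labelled 3 (adjusted p = 0.053) and in set 1 alone (adjusted p = 0.068); betaTub60D did not differ detectably (log2 0.35, SE 0.21, adjusted p = 0.33).

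Other lists called by camera between the RNAi groups were lower in Rab5 RNAi for eye pigment (4 of 16 called lower, camera adjusted p = 3.9e-03), photoreceptor structure (6 lower and 1 higher of 17, 2.2e-03), fat body (2 of 12, 0.012), the unfolded protein response (3 of 21, 0.014), glycolysis (2 of 17, 0.0255), oxidative phosphorylation (2 of 63, 4.0e-03) and ribosomal proteins (1 higher of 86, median -0.14, 3.9e-03). They were higher for JAK/STAT (2 of 11, 0.012), apoptosis and JNK signalling (4 of 28, 0.014) and glia (2 of 16, 0.032). Adjusted over the list alone, the counts in the same order were 6 lower, 8 lower and 1 higher, 2, 3, 2, 0 and 0, then 4, 6 and 4 higher. With an estimated correlation the lowest of these was adjusted p = 0.35 with an estimated correlation, for JAK/STAT. In set 1 alone the lists for ribosomal proteins, oxidative phosphorylation, JAK/STAT, the unfolded protein response, glycolysis and glia did not pass (adjusted p from 0.34 to 0.71). Without Rab7-labelled 2 the apoptosis and JNK list did not pass (camera adjusted p = 0.0501). The replicate number as a block ended 5 list calls between the RNAi groups, and leaving out Rab5 RNAi 5 also ended 5.

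Between the RNAi groups 1111 genes were called, 469 higher and 642 lower in Rab5 RNAi, and 245 had a log2 of at least 1 in size. The groups did not overlap in 906 of them; over all genes tested 11.5% did not overlap, where chance gives 1.59%. The largest by the rule, on the same scale, were Cyp6a17 (log2 3.85, SE 0.16), GstD5 (3.28, SE 0.47), Osi19 (2.87, SE 0.38) and the antibacterial peptide Dro (2.72, SE 0.55) above, and the cuticle protein Cpr72Ec (-5.14, SE 0.55), Pdh (-4.96, SE 0.27), SPH93 (-4.82, SE 0.55) and Rh4 below. SPH93 did not pass with limma-voom (adjusted p = 0.061), nor Dro with the replicate number as a block (adjusted p = 0.054). The count was 682 when only these 2 groups were fitted and 725 without Rab7-labelled 3. With plain read totals, which moved the median log2 of all genes to 0.11, 74.0% of calls were higher, against 42.2% with the deposited scaling.

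Genes changed in both RNAi groups against the same controls numbered 192. Of these 81 were higher in both, among them y, RpLP2 and Hsp70Bb, 99 were lower in both, among them mthl8 and the cuticle protein Acp1, and 12 went in opposite directions. Opposite genes included Cyp4p1 (log2 0.90 in Rab5 RNAi and -1.04 in the Rab7-labelled libraries) and the cuticle protein Cpr76Bc (-1.93 and 0.90). Unchanged groups simulated against common controls shared 0.01, 0 and 0 such genes on average. Few genes are called where nothing changes, so these values had to lie near 0. Independent lists of the observed lengths would share 13.6, 14.6 and 28.3. With the controls divided so that each comparison used a different 2 of them, the counts averaged 27.2, 36.7 and 2.33. Fewer genes were called there, 713 to 1036 in Rab5 RNAi and 94 to 143 in the Rab7-labelled libraries, so the values for independent lists do not apply. Across genes, which are not independent replicates, the covariance of the changes was 0.0793, against 0.0167 in the simulation (a difference of 0.0625) and 0.0672 with divided controls. The correlation was 0.51, against 0.53 in the simulation, where there is no effect. Both RNAi groups carried an RNAi transgene, while controls carried a wild-type chromosome. Shared changes therefore cannot be told apart from effects of the transgenes or the lines' genetic background. For y and mthl8 such a cause is weighed below.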

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

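The rule for single libraries, the counts over other splits and the tests of read number, pseudocount and sets on rhodopsins were written before their results were seen. The tests of sex, muscle, batch, eye cell loss, strain variants and equal photoreceptor loss were chosen after the results they bear on were seen.

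A library was listed where its gap to the nearest other library of its group was large for the group's range, by Dixon's test. Over 93 values in 3 groups, 279 tests, 15 were listed, where chance gives about 1 in 20, or 13.95. Control 4 accounts for 6 of them: betaTub60D at 12.3 FPKM (others 9.02 to 9.24), Rh4 at 205.9 FPKM (others 423.1 to 466.8), prom at 43.5 FPKM (others 30.8 to 32.9) and GstT4 at 42.4 FPKM (others 33.5 to 34.4). The other 2 were the unnamed model on 3L from 23078801 to 23082324 at 8.08 FPKM (others 3.59 to 3.94) and the mitochondrial share of reads at 4.22% (others 5.21% to 5.41%). In Rab5 RNAi, alphaTub67C was 0.903 FPKM in replicate 3, RpS29 was 1981 FPKM in replicate 2 and SPH93 was 0.837 FPKM in replicate 5. In the Rab7-labelled libraries, replicate 3 stood apart for GstE1 (117.8 FPKM), Patj (23.3 FPKM) and Ccz1 (11.2 FPKM), and replicate 4 for the same unnamed model (0.339 FPKM). Among controls, GstD9 was 68.7 FPKM in replicate 3 and the mitochondrial transcript mt:tRNA:Gly-TCC 4.97 FPKM in replicate 1.

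Other splits of the libraries were fitted in the same way. For Rab5 RNAi against control, 1 of 100 splits (drawn from 126) gave as many genes as the real 1761, the real one itself, and the highest other gave 753. For the Rab7-labelled libraries against control, 1 of all 35 splits gave as many as the real 322, and the highest other gave 2. Between the RNAi groups 1 of 100 splits gave as many as the real 1111, and the highest other gave 730. The real split gave the most genes of those run in all 3 comparisons. With only 35 or 126 splits possible, this argues against chance but cannot exclude it. Splits that mix the groups also carry group differences in their spread, which can lower their counts. The split with 730 put Rab5 RNAi 2, 3 and 4 with Rab7-labelled 2 and 3, which is exactly the division into set 1 and set 2, so the samples hold a structure that the groups do not explain. With the set as a covariate the 3 counts were 2191, 526 and 1566.

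The first pattern weighed is that division of libraries of every group into 2 sets. An unequal sex composition cannot be told apart from other causes, since its markers disagree. The male-limited RNA roX2 had a log2 difference of -0.21 (95% interval -0.48 to 0.06) and roX1 of 0.05. Yp3, a yolk protein gene of females, had -1.10 (95% interval -1.63 to -0.57), with 5.29 to 52.1 FPKM over all libraries. The difference of tra was -0.65 and of dsx 0.43, with intervals that exclude 0, and those of msl-2, Sxl and fru include 0. The sets were found in these same values, so whether such an interval excludes 0 cannot count as evidence. Yp1 and Yp2, yolk protein genes as well, reached at most 0.735 and 1.21 FPKM in any library, and roX1 ran from 202.5 to 298.2 FPKM. These levels argue against a large share of females in any library, but Yp3 goes the other way. A larger share of muscle in some heads could raise the muscle genes of set 2. Heat shock genes had a median of -0.38 between the sets, against -0.02 for all genes. That difference cannot decide on muscle share, since the level of heat shock genes in muscle and other tissues was not measured here. A library or collection batch cannot be told apart from other causes, since no label names one, though the sets partly followed the replicate numbers. Across genes, the set difference in Rab5 RNAi correlated at 0.26 with that in the Rab7-labelled libraries. The best other 2-against-2 split gave 0.023 in size, and single Rab7-labelled libraries against the rest 0.17 to 0.22. In controls the set split gave 0.16, the best other 2-against-2 split 0.091 and control 2 against the rest 0.20, in size. The sets were drawn from a direction shared by libraries of every group, so a higher correlation for the set split was favoured in advance. These correlations therefore cannot decide on a batch. An earlier assignment had control 1 in set 1; both were run, and no biological explanation other than sex and muscle share was tested.

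The second pattern is that 12 genes were near 0 (below 0.5 FPKM) in every library of 1 genotype and above 3 FPKM in every library of another: y, mthl8, CG11313, Osi19, Obp99d, Cyp6a17, CG42753, CG13071, CG12224 and 3 models without a name. Too few reads cannot be the cause, since the gene with the fewest had 134 over the libraries of the higher group. Loss of photoreceptors is argued against in the Rab7-labelled libraries for the 4 of these genes called lower in both RNAi groups. Their median there was -3.17, a fall they were selected for, while that of phototransduction genes was -0.17. Phototransduction genes report mainly photoreceptors, so loss of other eye cells cannot be judged from them. A strain variant stays open for all 12 genes and cannot be told apart from an effect of RNAi, since genotype and background go together in these samples and no reads were used here. y, like the eye pigment gene v, is a common marker on RNAi transgenes, and such a marker may be the source of either rise. While y was higher in both RNAi groups, v was called higher only in the Rab7-labelled libraries. In Rab5 RNAi v ran from 22.0 to 46.4 FPKM, against 26.7 to 33.3 FPKM in controls.

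The third pattern is the unequal fall of the 5 compound eye rhodopsins in Rab5 RNAi, from -4.02 for Rh4 to -0.49 for Rh6. Equal loss of all photoreceptors is argued against by their range of 3.53, with an SE of 0.40 for the difference between its ends. The range was 3.58 with a pseudocount of 0.1, against compression by the pseudocount, and 3.66 among set 1 libraries alone, against the sets. Unequal loss or regulation among photoreceptor types in Rab5 RNAi may therefore be a biological cause, as a hypothesis found and tested on the same data; loss of cells and lower expression per cell were not separated.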

How the results depend on the processing

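The settings based on sets and on plain read totals were chosen after the data were seen; all other settings were planned. A gene called neither in the reported fit nor under an alternative was taken to be the same there, whichever sign it had. A count was taken to be the same within 1.5 times. The fall of Rab5 kept its direction and its call throughout, from -1.03 to -0.95 against control and from -1.18 to -1.05 against the Rab7-labelled libraries with 1 library left out. Rab7 in the Rab7-labelled libraries ran from -0.09 to 0.01 with 1 library left out, was 0.04 in set 1 alone and was called under no setting. With 1 library left out, Rab5 RNAi against control gave 1176 to 1778 genes, the Rab7-labelled libraries 167 to 381 and the RNAi groups against each other 725 to 1064. Genes changed the same way in both, 180 in all, ranged from 108 to 195.

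Counts of the Rab7-labelled libraries (322) moved to 559 with only the 2 groups compared, 526 with the set as a covariate and 629 with control 1 moved to the other set. Those between the RNAi groups (1111) moved to 682 and, with control 1 moved, to 1739. The genes shared by both moved to 63.8 with 2 different controls for each comparison, to 285 and 337 with the set covariate and to 304 in set 1 with control 1. A covariate found in the data raises calls partly by its construction; the causes of the other moves were not tested. Plain read totals gave 2032, 274 and 1650 genes, of which 67.6%, 43.4% and 74.0% were higher, against 47.1%, 51.2% and 42.2% with the deposited scaling. The replicate number as a block gave 1946, 422 and 1169 genes. Of 12 pairs that share a number 7 correlated above 0.1, and 4 of 13 libraries correlated best with their own number. The sets partly followed the numbers: every replicate 1 was in set 2 (control 1 only barely), and every replicate 2 and 3 in set 1. Replicate 4 was in set 2 except in Rab5 RNAi. Whether the numbers pair the samples was therefore not settled. limma-voom on recovered reads gave 1706, 326 and 1108. The planned test with DESeq2 was not run, since FPKM were used here, and a comparison of counts with FPKM was not made.

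Of the settings for named genes against control, 43 ended and 7 made a call in Rab5 RNAi, against 2280 with no change, and 84 ended and 36 made one in the Rab7-labelled libraries, against 1294. Between the RNAi groups these were 5, 2 and 473. For lists, 16 of 261, 34 of 261 and 48 of 348 ended a call. No setting reversed a called direction. Depth limits genes with few reads, since 1 read in a gene of 1 kilobase is about 0.05 FPKM.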

Other observations

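These genes and lists lie outside the comparisons reported and were chosen after the values were seen; the lists themselves were fixed before. In Rab5 RNAi the drosopterin transporter gene bw and the ommochrome transporter gene st had log2 differences of -3.27 (SE 0.41) and -1.16 (SE 0.26), the only 2 called of 16 eye pigment genes (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.89; median 0.05, mean -0.22). Among 4 corneal lens genes retinin had -2.33 (SE 0.66) and Cpr72Ec -3.36 (SE 0.55) there. Crys, which codes for the lens protein Drosocrystallin, had a log2 of 1.52 (SE 0.18) in the Rab7-labelled libraries, in which no fall of Rab7 was detected. Of 21 genes of the unfolded protein response 7 fell and 0 rose in Rab5 RNAi (7 and 1 adjusted over the list alone; camera adjusted p = 0.15), with Herp at -0.49 (SE 0.07). Of 27 neuron markers 2 rose and 5 fell, with the synaptic protein nSyb at -0.57 (SE 0.11) and tyrosine hydroxylase ple at 1.18 (SE 0.20; camera adjusted p = 0.21). NimC4, a phagocytic receptor counted among hemocyte markers, had a log2 of 1.79 (SE 0.29), and TpnC4, a troponin, was the only muscle gene called of 24 (log2 2.34, SE 0.20). The lipid-binding genes Npc2g and Npc2h had -1.42 and -1.56.

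The other lists tested in Rab5 RNAi did not pass camera either. Of 27 immune signalling genes 6 rose and 3 fell (camera adjusted p = 0.21; median 0.11, mean -0.03), of 66 cytochrome P450 genes 6 and 8 (0.42), of 29 cuticle protein genes 3 and 8 (0.64), of 28 odorant binding proteins 3 and 5 (0.15) and of 13 circadian genes 1 and 3 (0.26). Mitochondrial transcripts had 2 higher of 22 there (0.090). In the Rab7-labelled libraries cuticle protein genes rose in 5 and fell in 3 cases (camera adjusted p = 0.12) and cytochrome P450 genes rose in 4 and fell in 5 (0.92).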
